A study of Mus musculus with 2 samples.

How the data were processed

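The series holds a gene expression sample and a hashtag sample of 1 10x Genomics 3' library (2 GEO samples, with files for the expression sample only, whose matrix also carries the hashtag counts). CD45+ cells were sorted from MC38 tumours of mice with human Fc gamma receptors, implanted with 2000000 cells and given 2 injections of 100 µg antibody 3 days apart. The authors made a matrix of raw UMI counts per feature and barcode with Cell Ranger 9.0.0 on a combined GRCh38 and GRCm39 reference, per the file headers and feature names, and no normalization had been applied to these deposited counts. It holds 38606 human genes, 33696 mouse genes, 6 hashtags and 2965363 barcodes. The deposited cell table gives a treatment, a cell type and a cluster for 19210 cells, without library or mouse. How the authors filtered, demultiplexed and clustered the cells is not given in the sources used here.

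Cells of this library were taken as the 8767 table entries whose barcode had at least 1000 mouse UMIs in the matrix. Of these, 33 whose top hashtag belonged to another treatment and 18 with a repeated barcode were left out, which leaves 8716 cells. The other 10443 entries have too few UMIs here and were used for shares only, in the closing section. Each hashtag fell in 1 treatment, so each was taken as 1 mouse and mice of a treatment were numbered in hashtag order; this gives 2 Untreated, 2 N297A, 1 GA-aFuc and 1 GITR/Syn GA-aFuc mouse. The top hashtag held a median of 96.2% of a cell's hashtag UMIs. The labels call the control both PBS and Untreated; Untreated is used. Cell types are the deposited names. No doublet caller was run, and the sources do not say whether the authors removed doublets. Doublets of different mice would show 2 hashtags. The top hashtag's share had its 1st percentile at 79.9%, with 0 cells under 50%, a cut that doublets of 2 mice would seldom fall below. This covers only cells that the authors kept: of 4198 barcodes outside the annotation, 1317 had a second hashtag over 20%. Doublets within a mouse would not show, and leaving out the top 5% of cells by UMIs is the alternative that weighs them. Chromosome positions are not given, since the annotation at hand is of another mouse build.

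UMI counts were summed per mouse and cell type with at least 20 cells in each mouse, which macrophages, monocytes, CD8 T cells, NK cells, cDC2 and all dendritic cells together (DC) had. edgeR 4.0.16 (R 4.3.3, limma 3.58.1) fitted the 4 treatments of the 6 mice in 1 model with TMM normalization, filterByExpr and the robust quasi-likelihood test, leaving 2 residual degrees of freedom. The genes tested numbered 13532 in macrophages, 11428 in monocytes, 9768 in CD8 T cells, 9228 in NK cells, 7953 in DC and 5920 in cDC2. P-values were adjusted by Benjamini-Hochberg within a cell type and comparison, with a threshold of 0.05. Counts of genes at an unadjusted p under 0.05 are to be read against the genes tested. A share of 0.05 of these would lie there if no gene differed. Totals over 5 cell types leave out cDC2, which are part of DC. The spread of a group with 1 mouse was taken from the groups with 2. On simulated data made from these counts, a 2-fold change was found in 17% (DC, 1 against 2 mice) to 71.1% (macrophages, 2 against 2 mice) of changed genes, and a 4-fold change in 65.3% to 95.9%, with 2 to 13 false calls. The simulated spread followed the trend with expression level, and no UMIs were gathered in single cells. These rates therefore do not cover genes with a larger spread or genes carried by 1 cell.

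The gene lists (19), comparisons and the rule for naming genes were fixed before the data were examined. Named genes are the 10 with the largest change in each direction among those past the threshold whose mice do not overlap between groups and whose higher group has at least 10 CPM, and up to 4 members of each list past 0.05 adjusted over that list alone. For comparisons without a test the rule takes genes with at least 50 UMIs in the higher group and the largest CPM ratios of at least 2, and list members by ratio; its use for CD4 T cells, too few for a test, was chosen after cell numbers were seen. The report prints part of the genes the rule takes. Segments of antigen receptors, mitochondrial genes and sex-linked genes were left out of the top lists. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The preset calls are given with their estimated-correlation p because none of them passes with it or with fry. Camera compares the genes of a list with the other genes, so a small preset p does not measure the spread between mice. With 2 residual degrees of freedom, not passing in the other versions does not show that a list is unchanged. Shares were compared by two-sided exact permutation tests over mice. Receptor levels are CPM of all mouse UMIs per mouse and cell type, compared between types with edgeR and mouse as a block; free RNA is the sum of 163010 barcodes with fewer than 50 UMIs (2355758 UMIs). Shares of cells with a UMI were taken after thinning to 2000 UMIs per cell.

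Alternatives were DESeq2 1.42.0, limma-voom, upper-quartile normalization, no filter or a mean count of 10, an adjusted p under 0.1, only the 2 treatments compared, thinned totals, leaving out each mouse, leaving out the top 5% of cells by UMIs, a filter at 500 genes and 10% mitochondrial UMIs, other denominators, centred log-ratios, marker naming and free RNA subtraction. Added after the data were seen were the comparison of Fc-enhanced with other mice, removal of the top cell of each gene, CD4 T cells at 10 cells per mouse, and Tregs against CD4 T cells at 10 cells. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The hashtag sample's own reads and the tumour volumes of the study were not analysed here.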

Results

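Single-cell RNA counts and hashtag counts were measured in CD45+ cells sorted from subcutaneous MC38 tumours, a mouse colon carcinoma line, grown in mice that carry human Fc gamma receptors. Mice were given hIgG1 antibodies against mouse GITR, the costimulatory receptor encoded by Tnfrsf18, or were Untreated. The antibodies were named N297A (agonist, Fc-null), GA-aFuc (agonist, Fc enhanced) and GITR/Syn GA-aFuc (non-agonist, Fc enhanced). By these labels they differ in agonism as well as in Fc class, and what Syn stands for is not given. The labels give a design of 3 mice per treatment. The library held 6 mice: 2 Untreated, 2 N297A, 1 GA-aFuc and 1 GITR/Syn GA-aFuc. After matching barcodes, 8716 annotated cells were used: 1484 and 1519 from Untreated replicates 1 and 2, 1485 and 1420 from N297A replicates 1 and 2, 1429 from the GA-aFuc mouse and 1379 from the GITR/Syn GA-aFuc mouse. Their mouse-gene UMIs came to 18562307, 19339165, 18628269, 17977401, 19141170 and 16479710 in the same order, with median UMIs per cell between 11259 and 12940. By the deposited names the cells were 4104 macrophages, 2486 monocytes, 907 CD8 T cells, 723 NK cells, 200 cDC2, 97 CD4 T cells, 74 regulatory T cells (Tregs), 57 mregDC (mature dendritic cells), 47 cDC1 and 21 pDC. Cells of 1 mouse are not replicates: each test of a gene or a share took mice as the replicates. The camera list tests set the genes of a list against the other genes. Their p-values at the preset correlation therefore do not measure the spread between mice. The GA-aFuc and GITR/Syn GA-aFuc groups held 1 mouse each, and in every test the lone mouse was assumed to vary like the Untreated and N297A mice.

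The expression of the antibodies' target was compared between cell types. Tnfrsf18 (ENSMUSG00000041954) was highest in Tregs, at 871 ± 224 CPM (mean ± SD, n = 6 mice). CD4 T cells followed at 345 ± 107 CPM, CD8 T cells at 251 ± 43.6 CPM and NK cells at 145 ± 29.3 CPM. Macrophages (2.55 ± 0.547 CPM) and monocytes (4.88 ± 1.61 CPM) lay below the free RNA level of 50.1 CPM. mregDC were at 101 ± 59.7 CPM and cDC2 at 33.5 ± 11.1 CPM. In tests with mouse as a block, Tnfrsf18 was higher in Tregs than in CD8 T cells of the 4 mice with at least 10 Tregs, a minimum chosen after the data were seen (log2 difference 1.85, SE 0.18, adjusted p = 1.39e-08). It was higher in CD8 T cells than in NK cells of 6 mice (log2 difference 0.76, SE 0.12, adjusted p = 0.000416). After thinning every cell to 2000 UMIs, 75.3% of Tregs, 47.4% of CD4 T cells, 34.2% of CD8 T cells and 23.4% of NK cells held a Tnfrsf18 UMI, against 0.367% of macrophages, the background.

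Human Fc gamma receptor transcripts, the receptors for the antibodies' Fc part in these mice, were counted in the same cells. FCGR3B was the most abundant, at 3611 ± 280.5 CPM in macrophages (n = 6 mice), 2901 ± 261 CPM in monocytes and 1049 ± 174 CPM in cDC2, and it supplied 53.1% of all human-gene UMIs. FCGR2A, an activating receptor, reached 1062 ± 152 CPM in macrophages and 853 ± 152 CPM in monocytes. The inhibitory receptor FCGR2B had the opposite order: cDC2 held 1388 ± 232 CPM, monocytes 1083 ± 57.6 CPM and macrophages 344 ± 78.1 CPM. Macrophages lay below monocytes (log2 difference -1.78, SE 0.10, adjusted p = 8.09e-06) and cDC2 above them (log2 difference 0.46, SE 0.07, adjusted p = 1.47e-05). The high-affinity receptor FCGR1A was higher in macrophages (222 ± 55.8 CPM) than in monocytes (134 ± 33.8 CPM; log2 difference 0.63, SE 0.04, adjusted p = 7.71e-11), against 8.16 CPM in CD8 T cells. FCGR3A, which mediates killing by NK cells, was at 238 ± 18.9 CPM in macrophages and at 95.9 ± 52.3 CPM in NK cells. The NK level was not separated from that of CD8 T cells (84.4 ± 52.5 CPM; log2 difference of CD8 from NK -0.25, adjusted p = 0.205). Without the GA-aFuc mouse NK cells lay above CD8 T cells (log2 difference of CD8 from NK -0.43, adjusted p = 0.0154). Free RNA held 1783 CPM of FCGR3B, 484 of FCGR2A, 506 of FCGR2B, 126 of FCGR3A and 94.7 of FCGR1A, so FCGR2B in macrophages, FCGR3B in cDC2 and FCGR3A in NK cells lay below the free RNA itself. Only part of a cell's UMIs comes from free RNA: CD8 T cells, taken to lack these genes, held 173 CPM of FCGR3B and 56.2 CPM of FCGR2B. With the CD8 T cell level subtracted, cDC2 had 877 CPM of FCGR3B and macrophages 287 CPM of FCGR2B. FCGR3A went to 154 CPM in macrophages and 11.6 CPM in NK cells, so whether NK cells hold it above background stays open. FCGR2C reached at most 5.89 CPM in any type, and FCGRT had 0 UMIs. Of the mouse receptors, Fcgr4 had 1 UMI in macrophages, while Fcgr2b was at 747 ± 20.1 CPM in monocytes. FCGR3A and FCGR3B are near-identical in sequence, and FCGR2C is close to both FCGR2A and FCGR2B. The division of reads between FCGR3A and FCGR3B, and between FCGR2C and the other FCGR2 genes, is therefore uncertain. FCGR2A and FCGR2B were told apart at least in part: their log2 differences of cDC2 from monocytes were -2.29 and 0.46.

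**Figure D1:**
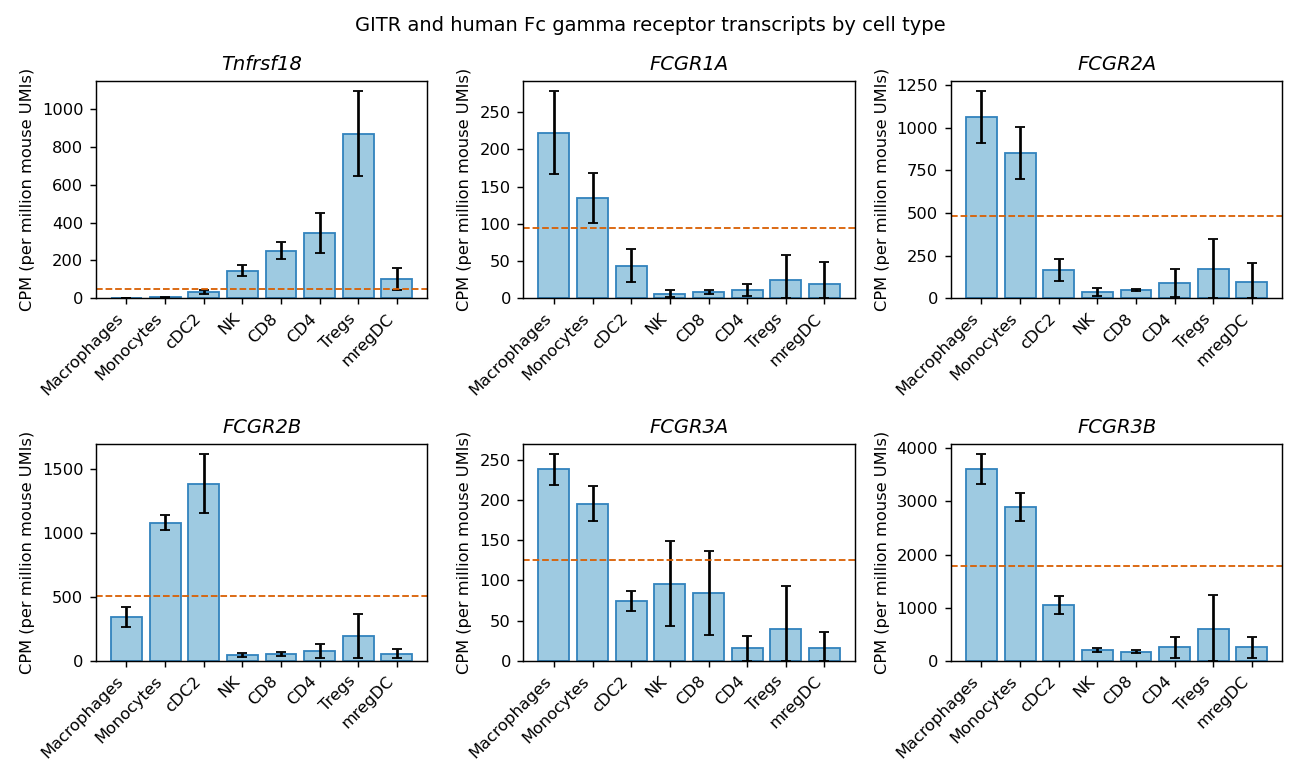
Levels (CPM of mouse UMIs) of Tnfrsf18 and of 5 human Fc gamma receptor genes in 8 cell types. Bars are means over the 6 mice with SD, and the dashed orange line is the free RNA level. Tnfrsf18 is highest in Tregs and FCGR2B in cDC2.

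Cell type shares were compared to see which populations differed between the treatments. Tregs, the cells with the highest Tnfrsf18, were 0.210% (3 of 1429 cells, 0.0433 to 0.612%) of the GA-aFuc mouse and 0.218% (3 of 1379 cells, 0.0449 to 0.634%) of the GITR/Syn GA-aFuc mouse. The Untreated mice held 0.741% (11 of 1484 cells, 0.371 to 1.32%) and 0.856% (13 of 1519 cells, 0.456 to 1.46%). The N297A mice held 1.35% (20 of 1485 cells, 0.825 to 2.07%) and 1.69% (24 of 1420 cells, 1.09 to 2.50%). Intervals are 95% Clopper-Pearson and cover counting error only. The mean of the 2 mice given an Fc-enhanced antibody was 0.214%, against 1.16% in the other 4 (difference -0.945 percentage points), a grouping chosen after the data were seen. Its two-sided exact permutation p was 0.133, where the 15 splits allow 0.0667 at the smallest (adjusted p = 0.952). N297A mice had more Tregs than Untreated mice (1.52% against 0.799%, difference 0.720 percentage points, n = 2 and 2, exact permutation p = 0.333, the smallest this design allows). With cells renamed by fixed marker lists this difference was -0.45, but the cells so named Tregs held 100 deposited CD8 T cells beside 60 deposited Tregs. Barcodes of this library with Cd3 and Foxp3 UMIs, annotated or not, were 1.58% and 1.46% in N297A and 0.992% and 0.892% in Untreated mice. The table's cells outside this library had the opposite order (0.448%, 0.194 to 0.881% against 0.624%, 0.312 to 1.11%, on 8 and 11 Tregs), so the direction stays open. Macrophages made up 52.5% of cells with the Fc-enhanced antibodies and 44.6% without (n = 2 and 4, exact permutation p = 0.133). Monocytes made up 24.2% and 30.5% (exact permutation p = 0.2), which the cells outside this library did not repeat: Untreated lay below both Fc-enhanced groups there and N297A above them. mregDC were 0.447% in N297A and 0.832% in Untreated mice (n = 2 and 2, exact permutation p = 0.333), and the cells outside this library had the opposite order (0.560%, 0.269 to 1.03% against 0.454%, 0.196 to 0.892%), so this direction stays open as well. None of the shares passed an adjusted p of 0.05, which these numbers of mice cannot reach.

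**Figure D2:**
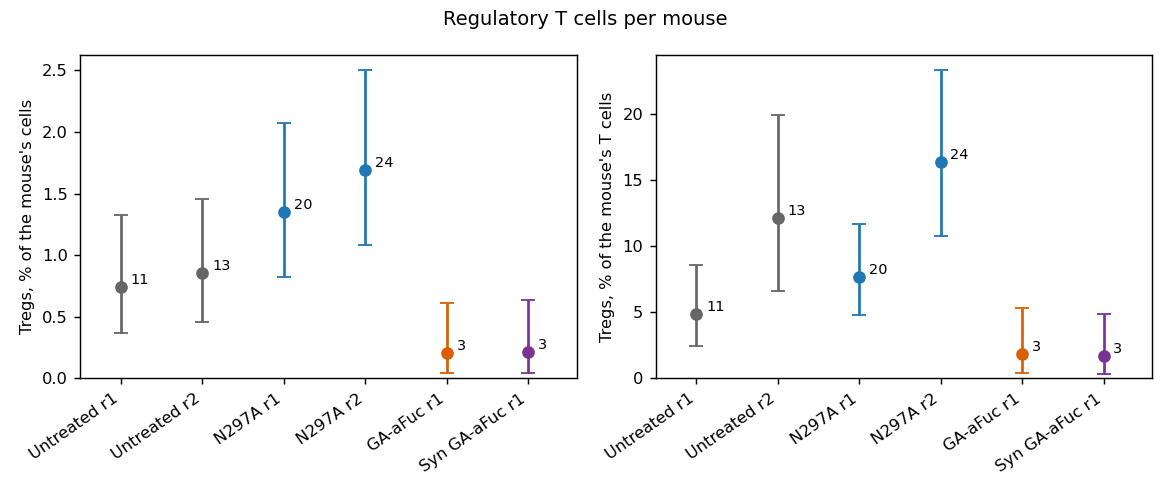
Tregs as a percentage of each mouse's annotated cells, with 95% Clopper-Pearson intervals and numbers of cells. The GA-aFuc and GITR/Syn GA-aFuc mice, at 0.210% and 0.218%, lie below the Untreated and N297A mice.

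N297A against Untreated asks what an antibody that binds GITR without engaging Fc receptors changes (2 against 2 mice). In dendritic cells of all subsets, Cxcl9, an interferon-induced chemokine that attracts CXCR3+ T cells, rose (log2 change 1.16, SE 0.21, adjusted p = 0.0257). In cDC2 alone it rose from 576 to 1465 CPM (log2 change 1.34, SE 0.20, adjusted p = 0.000841). The lymph-node homing receptor Ccr7 (log2 change -0.94, SE 0.20, adjusted p = 0.0423) and Cacnb3 (log2 change -1.48, SE 0.30, adjusted p = 0.0203), both carried by mature dendritic cells, fell. The chemokine Ccl5 (log2 change -1.70, SE 0.22, adjusted p = 0.00374) and Slc44a5 (log2 change -4.02, SE 0.48, adjusted p = 0.000181) fell as well. In all, 1 gene rose and 23 fell in dendritic cells, among them Agap1 (-2.84 ± 0.46) and Syn3 (-2.48 ± 0.41). Slco5a1 and Gm16685 had 0 UMIs in both N297A mice. The fixed list of dendritic cell maturation lay lower, with 9 of 22 members past 0.05 adjusted over the list alone and 2 over all genes (median log2 change -0.76; camera adjusted p = 1.25e-08, and adjusted p = 0.512 with an estimated correlation). The type I interferon list lay higher, with 5 of 27 members up adjusted over the list alone (median 0.42; adjusted p = 1.19e-06, and adjusted p = 0.759 with an estimated correlation). These sums mix subsets whose numbers differed: the mregDC, which carry Ccr7 and Cacnb3, were 12 and 13 cells in the Untreated and 7 and 6 in the N297A mice. Slc44a5 passed whichever mouse was left out (adjusted p up to 0.0174). Cxcl9 in dendritic cells no longer passed with N297A replicate 2 or Untreated replicate 2 left out (adjusted p up to 0.458), nor did Ccl5 and Agap1 with either Untreated mouse left out (adjusted p up to 0.229 and 0.104). Cacnb3 in dendritic cells no longer passed with N297A replicate 1 or either Untreated mouse left out (adjusted p up to 0.425), nor did Ccr7 with the GITR/Syn GA-aFuc mouse, either N297A mouse or either Untreated mouse left out (adjusted p up to 0.407). Syn3 in dendritic cells no longer passed with Untreated replicate 2 left out (adjusted p up to 0.206). Cxcl9 in cDC2 no longer passed with N297A replicate 2 or Untreated replicate 1 left out (adjusted p up to 1.00).

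Outside dendritic cells few genes differed between N297A and Untreated. Monocytes had 1 call, Thbs1, which encodes the matrix protein thrombospondin (log2 change 0.80, SE 0.09, adjusted p = 0.0370). CD8 T cells had the receptor gene Klra5 up (log2 change 1.49, SE 0.27, adjusted p = 0.0436) and Cxcl9 down (log2 change -1.21, SE 0.18, adjusted p = 0.00497). For Cxcl9, 89 of its 193 UMIs in the higher Untreated mouse came from 1 cell. NK cells had Apoe down (log2 change -0.89, SE 0.13, adjusted p = 0.0155), with 239 of 712 UMIs of 1 mouse in 1 cell. Apoe is one of the fixed macrophage markers, and whether its UMIs in NK cells came from macrophage RNA was not tested. Macrophages had 0 genes past 0.05 by edgeR, 0 by DESeq2 and 0 by limma-voom. Of 13532 genes tested there, 445 had an unadjusted p under 0.05, fewer than would lie there if no gene differed. In monocytes 26 of 27 type I interferon genes had a positive change (median 0.23; adjusted p = 0.000146, and adjusted p = 0.911 with an estimated correlation). The cell cycle list lay higher in NK cells (median 0.46; adjusted p = 6.8e-06, and adjusted p = 0.773 with an estimated correlation). Over 5 cell types (macrophages, monocytes, CD8 T cells, NK cells and dendritic cells), 28 genes passed. That number was 3 without Untreated replicate 2, 148 without N297A replicate 1 and 198 without N297A replicate 2. Thbs1 in monocytes no longer passed with Untreated replicate 2 or either N297A mouse left out (adjusted p up to 0.346). Klra5 in CD8 T cells no longer passed with the GA-aFuc mouse or either Untreated mouse left out (adjusted p up to 0.937), nor did Cxcl9 with either Untreated mouse left out (adjusted p up to 0.697). Apoe in NK cells no longer passed with N297A replicate 2 or either Untreated mouse left out (adjusted p up to 0.998).

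GA-aFuc against Untreated gives the change with the Fc-enhanced agonist (1 against 2 mice). Monocytes had 19 genes up and 3 down (limma-voom called 4 and 0). The inducible nitric oxide synthase Nos2 rose from 36.9 to 154 CPM (log2 change 2.08, SE 0.17, adjusted p = 0.00119). Slc7a2, a transporter of its substrate arginine, rose with it (log2 change 2.57, SE 0.25, adjusted p = 0.0162). The endotoxin receptor Tlr4 (1.02 ± 0.15, SE), the chemokine Pf4 (1.57 ± 0.21), the uridine phosphorylase Upp1 (1.16 ± 0.13) and the receptor P2ry14 (1.01 ± 0.13) rose as well. So did Cd274, which encodes PD-L1 (log2 change 0.83, SE 0.13, adjusted p = 0.0372), and the interferon-induced Ifi44 (log2 change 0.95, SE 0.12, adjusted p = 0.0200). Ccr2, the receptor that brings monocytes into tissue, fell from 509.5 to 291 CPM (log2 change -0.81, SE 0.11, adjusted p = 0.0226). Mid1 (-2.96 ± 0.39) and S100a4 (-0.66 ± 0.10) fell too. The list of hypoxia and glycolysis lay higher (median 0.30 over 20 members, 2 up adjusted over the list alone and 0 over all genes; adjusted p = 7.04e-05, and adjusted p = 0.795 with an estimated correlation). Inflammatory cytokines and chemokines lay higher too (median 0.25, 3 of 20 up adjusted over the list alone; adjusted p = 0.00588, and adjusted p = 0.795 with an estimated correlation). Nos2 (adjusted p up to 0.00228), Slc7a2, Tlr4, Pf4, Upp1, P2ry14, Ccr2 and Mid1 passed whichever of the other mice was left out. S100a4 in monocytes no longer passed with either N297A mouse left out (adjusted p up to 0.0540), nor did Cd274 with Untreated replicate 2 left out (adjusted p up to 0.0852).

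**Figure D3:**
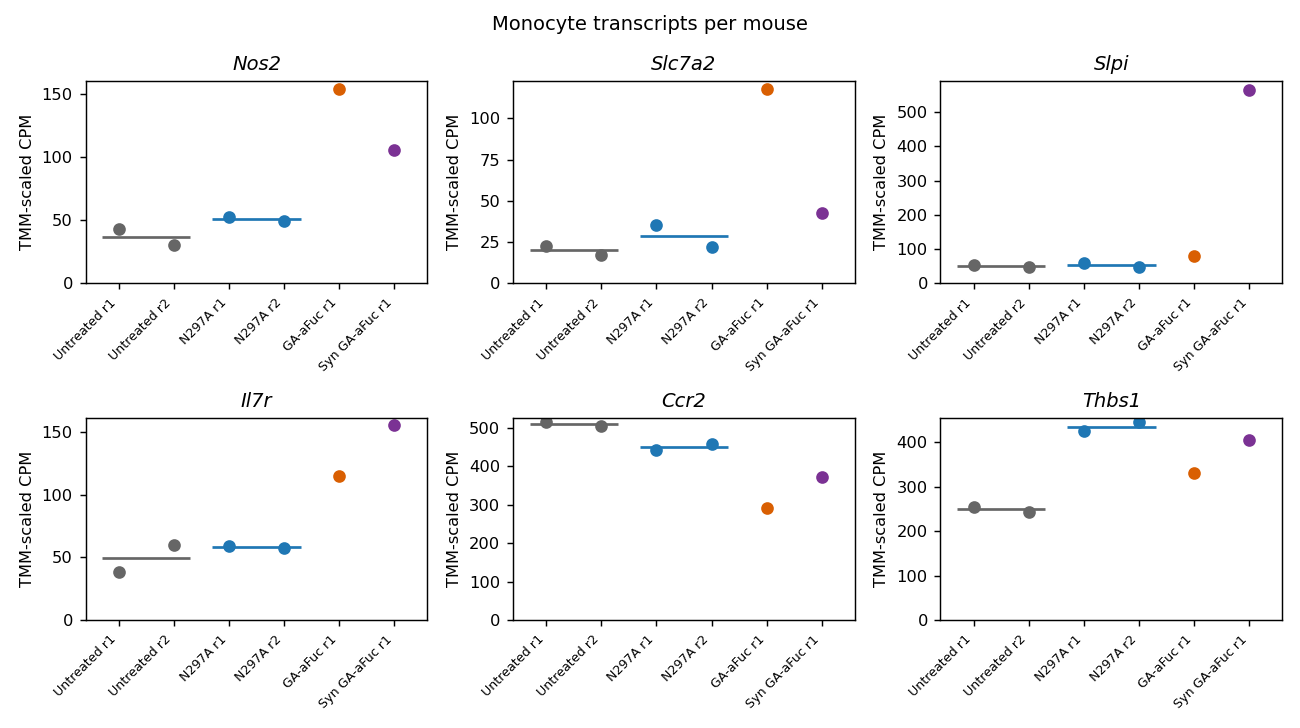
TMM-scaled counts (CPM) of 6 genes in the monocytes of each of the 6 mice, with a line at the mean of each 2-mouse group. Nos2 and Slc7a2 are higher in the GA-aFuc mouse than in the Untreated mice, Slpi is highest in the GITR/Syn GA-aFuc mouse, and Ccr2 is lowest in the GA-aFuc mouse.

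In the other cell types fewer genes changed with GA-aFuc. Macrophages raised Flt1, a receptor for vascular growth factors (log2 change 1.58, SE 0.14, adjusted p = 0.0185). The unnamed gene Gm42031 rose in macrophages (log2 change 2.99, SE 0.16, adjusted p = 0.000495) and in monocytes (3.44 ± 0.21). It was high in every larger cell type of this 1 mouse, so a trait of the mouse cannot be told apart from the antibody. NK cells lowered Ccl5, a T cell attracting chemokine (log2 change -1.32, SE 0.17, adjusted p = 0.0210). In NK cells Gzmg (4.06 ± 0.31), Cxcl2, Ccl2 and Ccl7 also passed, but 432 of 1092, 153 of 168, 81 of 107 and 75 of 105 UMIs came from 1 cell. CD8 T cells had Klra5 up (2.51 ± 0.29, SE) and Tgm2 (-2.10 ± 0.36), Pid1 (-2.07 ± 0.42) and Cxcl9 (-1.85 ± 0.25) down. Tgm2, Pid1, Cxcl9 and Klra5 did not pass without the top cell of each gene (adjusted p from 0.329 to 1.00). Gm42031 rose in CD8 T cells as well (3.28 ± 0.39). Of the others up in CD8 T cells, 4 rest on UMIs in at most 5 cells of the GA-aFuc mouse: Csf2 (55.9 against 0.548 CPM, 30 of 78 UMIs in 1 cell), Gzmg (48.0 against 2.22 CPM, 65 of 67 UMIs in 1 cell), Cox6a2 (36.6 against 0 CPM, 46 of 51 UMIs in 1 cell) and Ccr9 (28.0 against 1.70 CPM, 39 of 39 UMIs in 1 cell). In cDC2 the chemokines Ccl22 (log2 change 2.79, SE 0.56, adjusted p = 0.0321) and Ccl3 (log2 change 3.09, SE 0.59, adjusted p = 0.0219) rose, and Xylt1 fell (-3.08 ± 0.58). The dendritic cell maturation list lay lower in dendritic cells together (median -0.72, 6 of 22 members down adjusted over the list alone; adjusted p = 1.71e-06, and adjusted p = 0.675 with an estimated correlation), and this mouse held 6 mregDC. The type I interferon list lay higher in macrophages (median 0.25; adjusted p = 0.000272, and adjusted p = 0.869 with an estimated correlation). Over the 5 cell types 43 genes passed, against 180 without N297A replicate 1 and 144 without N297A replicate 2. Flt1 in macrophages no longer passed with either Untreated mouse left out (adjusted p up to 0.260). Ccl5 in NK cells no longer passed with the GITR/Syn GA-aFuc mouse or either Untreated mouse left out (adjusted p up to 0.316), nor did Gzmg with either N297A mouse left out (adjusted p up to 0.360). Cxcl2, Ccl2 and Ccl7 in NK cells no longer passed with either Untreated mouse left out (adjusted p up to 0.315, 0.411 and 0.765). Klra5, Tgm2, Pid1, Cxcl9, Gm42031, Csf2, Gzmg, Cox6a2 and Ccr9 in CD8 T cells no longer passed with either Untreated mouse left out (adjusted p up to 0.0681, 0.241, 0.909, 0.0681, 0.0681, 0.147, 0.244, 0.122 and 0.616). Ccl22, Ccl3 and Xylt1 in cDC2 no longer passed with N297A replicate 2 or either Untreated mouse left out (adjusted p up to 0.410, 0.478 and 0.491).

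GITR/Syn GA-aFuc against Untreated gives the change with the Fc-enhanced non-agonist (1 against 2 mice). Monocytes had 24 genes up and 0 down by edgeR, out of 761 genes at an unadjusted p under 0.05 (DESeq2 called 0 down and limma-voom 0). The number up was 13 with DESeq2, 6 with limma-voom, 4 with upper-quartile normalization and 13 without the top cell of each gene. Slpi, a secreted inhibitor of leukocyte proteases, had the firmest rise (log2 change 3.49, SE 0.14, adjusted p = 9.39e-07), with 1948 UMIs in 100 cells, 523 of them in 1 cell. Nos2 rose here too (log2 change 1.53, SE 0.17, adjusted p = 0.0140), as did Gclm, the modifier subunit of the enzyme that starts glutathione synthesis (log2 change 1.84, SE 0.20, adjusted p = 0.00940). The interleukin 7 receptor Il7r rose (log2 change 1.64, SE 0.21, adjusted p = 0.0355), and so did the lysosomal and lipid genes Gpnmb (2.52 ± 0.41, SE), Fabp5 (1.29 ± 0.18) and Ctsd (0.81 ± 0.12). Cxcl1, a neutrophil attractant, rose (3.70 ± 0.56), with 29 of 47 UMIs in 1 cell. Of 20 inflammatory genes 5 rose adjusted over the list alone and 2 over all genes (median 0.54; adjusted p = 9.32e-06, and adjusted p = 0.665 with an estimated correlation). In macrophages Slpi rose (3.18 ± 0.26; 152 of 258 UMIs in 1 cell) and so did the interferon gene Ifnb1, with 91 of 123 UMIs in 1 cell. The macrophage cell cycle list lay lower, with 15 of 22 members down adjusted over the list alone and 0 over all genes (median -0.57; adjusted p = 6.32e-14, and adjusted p = 0.714 with an estimated correlation). The macrophage type I interferon list lay higher (3 of 27 up adjusted over the list alone; adjusted p = 3.71e-07, and adjusted p = 0.714 with an estimated correlation). In monocytes Slpi, Nos2, Gclm and Cxcl1 passed whichever other mouse was left out. Gpnmb and Fabp5 in monocytes no longer passed with either Untreated mouse left out (adjusted p up to 0.0654 and 0.139), nor did Il7r with either N297A mouse left out (adjusted p up to 0.0756). Slpi and Ifnb1 in macrophages no longer passed with either Untreated mouse left out (adjusted p up to 0.122 and 0.122).

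CD8 T cells of the GITR/Syn GA-aFuc mouse differed from Untreated in 7 genes up and 8 down. The galectin gene Lgals3 (log2 change 1.04, SE 0.14, adjusted p = 0.000333), Ly6c2 (log2 change 0.64, SE 0.12, adjusted p = 0.0142), the cytokine gene Metrnl (1.04 ± 0.19, SE) and the adaptor Pag1 (0.89 ± 0.17) rose. Bach2, a repressor that keeps T cells in a memory state, fell (log2 change -1.30, SE 0.19, adjusted p = 0.000784). Tnfrsf4, the costimulatory receptor OX40, fell too (log2 change -1.70, SE 0.23, adjusted p = 0.000673). The naive and memory list lay lower (median -0.74 over 10 members; 1 up and 2 down adjusted over the list alone; adjusted p = 0.00136, and adjusted p = 0.461 with an estimated correlation). TNF receptor costimulation lay lower too (2 of 17 down adjusted over the list alone; adjusted p = 0.00582, and adjusted p = 0.461 with an estimated correlation). NK cells lowered Ccl5 (log2 change -1.48, SE 0.18, adjusted p = 0.0278), the NF-kB regulator Nfkbiz (log2 change -2.21, SE 0.34, adjusted p = 0.0194) and the kinase Pim1 (-1.30 ± 0.23). Apoe, one of the fixed macrophage markers, was lower in the NK cell sums too (-1.01 ± 0.18), and whether its UMIs there came from macrophage RNA was not tested. The effector list lay lower in NK cells (3 of 19 down adjusted over the list alone, adjusted p = 0.00567, and adjusted p = 0.561 with an estimated correlation). In cDC2 proliferation genes fell, among them the linker histone H1f5 (log2 change -4.03, SE 0.56, adjusted p = 0.000287), Top2a (-3.56 ± 0.58), Stmn1 (-3.13 ± 0.58) and Hmgb2 (-1.97 ± 0.33), while Mki67 had 0 UMIs in this mouse. Of 17 cell cycle genes measured in cDC2, 9 fell adjusted over the list alone and 5 over all genes (adjusted p = 1.26e-18, and adjusted p = 0.666 with an estimated correlation). The cDC2 sums hold 26 and 27 cells of the Untreated mice and 34 of this mouse. Without the top 5% of cells by UMIs H1f5, Top2a, Stmn1 and Hmgb2 did not pass (adjusted p = 0.996; log2 changes -2.92, -1.62, -2.34 and -0.98); whether fewer cells or fewer counts ended these calls was not separated. Without the top cell of each gene the adjusted p of H1f5 was 0.724. In dendritic cells together 0 genes passed by edgeR, 0 by DESeq2 and 0 by limma-voom (282 at an unadjusted p under 0.05). Over the 5 types 45 genes passed, against 205 without N297A replicate 1 and 205 without N297A replicate 2. Lgals3, Ly6c2, Metrnl and Pag1 in CD8 T cells no longer passed with either Untreated mouse left out (adjusted p up to 0.129, 0.551, 0.343 and 0.259), nor did Bach2 and Tnfrsf4 with Untreated replicate 2 left out (adjusted p up to 0.140 and 0.129). Ccl5 in NK cells no longer passed with either Untreated mouse left out (adjusted p up to 0.887), nor did Nfkbiz, Pim1 and Apoe with N297A replicate 2 or either Untreated mouse left out (adjusted p up to 0.887, 0.896 and 0.896). H1f5 and Hmgb2 in cDC2 no longer passed with Untreated replicate 1 left out (adjusted p up to 0.0844 and 0.0844), nor did Top2a and Stmn1 with either Untreated mouse left out (adjusted p up to 0.0952 and 0.217).

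GA-aFuc against N297A compares agonist antibodies that differ in Fc receptor engagement (1 against 2 mice). In monocytes Nos2 rose (log2 change 1.59, SE 0.17, adjusted p = 0.0131) and so did Gm42031 (4.20 ± 0.23, SE), the 2 calls there. NK cells, with 8 genes up and 3 down, lowered Ccl5 (log2 change -1.49, SE 0.18, adjusted p = 0.0110) and Pim1 (-1.11 ± 0.20). They raised AA467197 (log2 change 0.94, SE 0.16, adjusted p = 0.0110) and Lgals3 (0.86 ± 0.15). In CD8 T cells Gm42031 (3.86 ± 0.41) and Cox6a2 (36.6 against 0.248 CPM) were up whichever other mouse was left out, the latter with 46 of 51 UMIs in 1 cell; DESeq2 passed neither (adjusted p = 0.252 and 1). Csf2 and Ccr9 also passed there, on the cells named above. In cDC2 Ccl22, a chemokine that attracts CCR4+ T cells, rose (log2 change 3.10, SE 0.54, adjusted p = 0.00736). Cxcl9 (log2 change -1.33, SE 0.25, adjusted p = 0.0171) and Xylt1 (-3.36 ± 0.56) fell there. The monocyte hypoxia list lay higher (median 0.21; adjusted p = 0.00390, and adjusted p = 0.989 with an estimated correlation). The NK list of inflammatory chemokines lay higher too (3 of 11 up adjusted over the list alone; adjusted p = 0.00643, and adjusted p = 0.795 with an estimated correlation). Its members that passed rest on few cells: 153 of 168 Cxcl2, 81 of 107 Ccl2 and 75 of 105 Ccl7 UMIs of the GA-aFuc mouse came from 1 cell. Without the top cell their changes were 0.32, -0.14 and 0.88, and none passed (adjusted p 0.903 or more). Over the 5 types 19 genes passed, against 132 without N297A replicate 1. Csf2 and Ccr9 in CD8 T cells no longer passed with either Untreated mouse left out (adjusted p up to 0.0984 and 0.0984). Nos2 in monocytes no longer passed with N297A replicate 2 left out (adjusted p up to 0.190). Ccl5 in NK cells no longer passed with either Untreated mouse left out (adjusted p up to 0.250), nor did Pim1 and Lgals3 with either N297A mouse or either Untreated mouse left out (adjusted p up to 0.480 and 0.403). AA467197 in NK cells no longer passed with N297A replicate 2 or either Untreated mouse left out (adjusted p up to 0.250). Ccl22 and Cxcl9 in cDC2 no longer passed with N297A replicate 2 or Untreated replicate 1 left out (adjusted p up to 0.479 and 0.997), nor did Xylt1 with Untreated replicate 1 left out (adjusted p up to 0.150).

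GITR/Syn GA-aFuc against GA-aFuc compares a non-agonist with an agonist that the labels both call Fc enhanced (1 mouse each, with the spread taken from the Untreated and N297A pairs). In monocytes Slpi was higher (log2 change 2.81, SE 0.17, adjusted p = 9.17e-05) and Gm42031 lower (-3.99 ± 0.29, SE). In CD8 T cells Lgals3 (log2 change 0.83, SE 0.16, adjusted p = 0.0233) and Pag1 (log2 change 1.00, SE 0.20, adjusted p = 0.0331) were higher. Tnfrsf4 (log2 change -1.41, SE 0.25, adjusted p = 0.0171), Pim1 (-1.14 ± 0.21) and the NF-kB inhibitor Nfkbia (-1.07 ± 0.21) were lower. Gm42031 (-2.89 ± 0.46), Csf2, Ccr9, Gzmg and Cox6a2 were lower too, the last 4 on the same few cells of the GA-aFuc mouse. In all, 3 genes were up and 10 down. TNF receptor costimulation genes lay lower in CD8 T cells, with 1 up and 7 down of 17 adjusted over the list alone and 0 up and 2 down over all genes (adjusted p = 0.00113, and adjusted p = 0.618 with an estimated correlation). Interferon gamma response genes lay lower in macrophages (median -0.34; adjusted p = 9.63e-06, and adjusted p = 0.989 with an estimated correlation). In monocytes they lay lower too (median -0.30; adjusted p = 0.00028, and adjusted p = 0.796 with an estimated correlation). The cell cycle list lay lower in cDC2 (median -1.73; adjusted p = 8.54e-16, and adjusted p = 0.781 with an estimated correlation). Without the top 5% of cells by UMIs the changes of Top2a and H1f5 turned from -3.68 and -3.59 to 0.43 and 0.43, that of Pclaf, which had not passed, turned too, and Hmgb2 passed (adjusted p = 0.0433) only with no mouse left out. In dendritic cells together 0 genes passed by edgeR, 0 by DESeq2 and 0 by limma-voom (313 at an unadjusted p under 0.05). Over the 5 types 19 genes passed, against 8 and 10 without Untreated replicates 1 and 2, and 79 and 64 without N297A replicates 1 and 2. Lgals3, Pag1, Tnfrsf4, Pim1, Nfkbia, Gm42031, Csf2, Ccr9, Gzmg and Cox6a2 in CD8 T cells no longer passed with either Untreated mouse left out (adjusted p up to 0.269, 0.264, 0.248, 0.248, 0.269, 0.248, 0.248, 0.328, 0.248 and 0.248).

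The mice given either Fc-enhanced antibody were also compared with the mean of the Untreated and N297A groups (2 against 4 mice), a comparison chosen after the data were seen. In this fit each Fc-enhanced antibody was its own group of 1 mouse. The SEs and p-values therefore leave out the spread between these 2 mice. In NK cells Ccl5 was lower, 818 against 2291 CPM (log2 change -1.48, SE 0.13, adjusted p = 0.000579). Nfkbiz (log2 change -1.60, SE 0.21, adjusted p = 0.000579), Pim1 (-1.20 ± 0.15) and Ust (-0.94 ± 0.15) were lower too, as was Gzma, which encodes the cytotoxic granzyme A (log2 change -0.43, SE 0.07, adjusted p = 0.0148). Lgals3 was higher (log2 change 0.67, SE 0.11, adjusted p = 0.00584). Of 19 effector genes measured in NK cells 3 fell adjusted over the list alone and 2 over all genes (adjusted p = 0.0167, and adjusted p = 0.819 with an estimated correlation). In monocytes 18 genes were higher and 2 lower. Nos2 (log2 change 1.56, SE 0.12, adjusted p = 0.00075), Slpi (2.03 ± 0.10), Slc7a2 (1.57 ± 0.19), Il7r (1.31 ± 0.15), Cxcl1 (3.75 ± 0.43) and the interleukin 1 gene Il1a (1.04 ± 0.15) were among the higher genes. Ccr2 (-0.54 ± 0.08) and Mid1 (-1.87 ± 0.25) were lower. The monocyte inflammatory list had 6 of 20 members up adjusted over the list alone and 3 over all genes (adjusted p = 1.59e-05, and adjusted p = 0.744 with an estimated correlation). Hypoxia and glycolysis had 5 of 20 up adjusted over the list alone and 0 over all genes (adjusted p = 1.59e-05, and adjusted p = 0.744 with an estimated correlation). Cell cycle genes lay lower in macrophages (9 of 22 down adjusted over the list alone; adjusted p = 5.97e-11, and adjusted p = 0.654 with an estimated correlation). Type I interferon genes lay higher there (adjusted p = 1.36e-07, and adjusted p = 0.654 with an estimated correlation). In dendritic cells together 0 genes passed by edgeR, 0 by DESeq2 and 0 by limma-voom (284 at an unadjusted p under 0.05). Over the 5 types 35 genes passed, against 278 and 93 without N297A replicates 1 and 2 and 66 without Untreated replicate 1. Nos2 and Cxcl1 in monocytes passed whichever mouse was left out. Slpi in monocytes no longer passed with the GITR/Syn GA-aFuc mouse left out, where its log2 change was 0.62. Nor did Slc7a2 and Mid1 with the GA-aFuc mouse left out, where their log2 changes were 0.83 and -0.88. Each of these values is thus largely that of 1 mouse. Il7r in monocytes no longer passed with the GITR/Syn GA-aFuc mouse or either N297A mouse left out (adjusted p up to 0.134), nor did Il1a with the GA-aFuc mouse or the GITR/Syn GA-aFuc mouse left out (adjusted p up to 0.0975). Ccr2 in monocytes no longer passed with the GA-aFuc mouse or N297A replicate 2 left out (adjusted p up to 0.380). Ccl5 and Pim1 in NK cells no longer passed with either Untreated mouse left out (adjusted p up to 0.288 and 0.288), nor did Nfkbiz and Gzma with the GITR/Syn GA-aFuc mouse or either Untreated mouse left out (adjusted p up to 0.288 and 0.813). Ust in NK cells no longer passed with the GA-aFuc mouse, N297A replicate 2 or either Untreated mouse left out (adjusted p up to 0.387), nor did Lgals3 with the GA-aFuc mouse or either Untreated mouse left out (adjusted p up to 0.656).

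**Figure D4:**
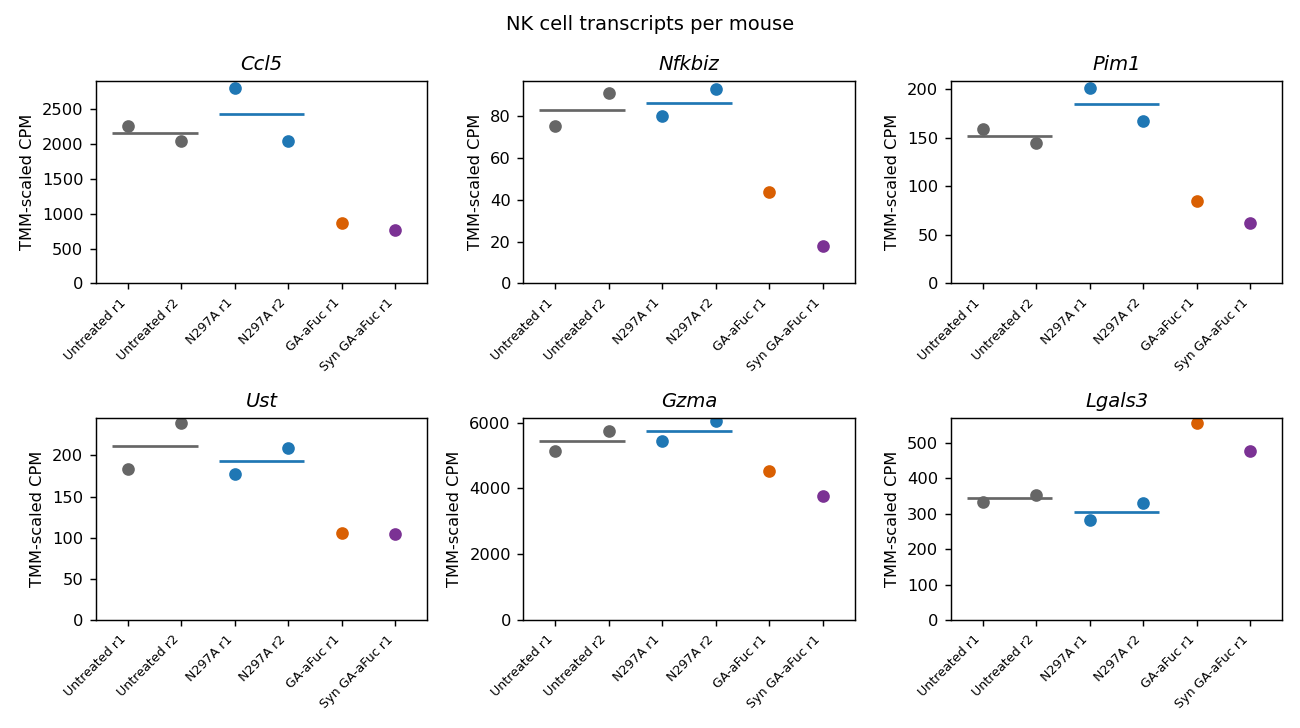
TMM-scaled counts (CPM) of 6 genes in the NK cells of each of the 6 mice, with a line at the mean of each 2-mouse group. Ccl5, Nfkbiz, Pim1, Ust and Gzma are lower and Lgals3 higher in the GA-aFuc and GITR/Syn GA-aFuc mice than in the other 4 mice.

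CD4 T cells, the cells named in the series title, numbered 12 to 24 per mouse, under the minimum of 20 for a test in most mice, so their levels are given as CPM of summed counts without a test, with exact 95% Poisson intervals that cover counting error only. Against N297A, the CD4 T cells of the GA-aFuc mouse held less Ikzf2, which marks regulatory cells (117 CPM, interval 75.7 to 173, against 669.6, interval 561 to 793). They also held less Tnfrsf4 (169 CPM, interval 118 to 233, against 595, interval 493 to 712) and less of the interleukin 21 receptor Il21r (93.6 CPM, interval 57.2 to 145, against 275, interval 207 to 358). Ccl4 was higher with GA-aFuc than Untreated (3844 against 41.8 CPM), but 813 of 821 UMIs came from 1 cell. With GITR/Syn GA-aFuc, 73 of 73 Ccl3 UMIs and 148 of 148 Ccl1 UMIs came from 1 cell. The deposited CD4 group held a cluster of 58 cells with Trdc and Il17a (312 and 155 CPM), genes of gamma-delta and interleukin 17 producing T cells. It also held a cluster of 39 cells with Ccl1 and Tnfsf11 (629 and 482 CPM), which had more Cd8a (266 CPM, in 35.9% of cells) and Cd8b1 (393 CPM, in 38.5%) than Cd4 (227 CPM, in 53.8%). The macrophage gene C1qa was at 703 CPM in the larger cluster (58.6% of cells), at 85.7 in the other (48.7%) and at 1022 in the Tregs (66.2%), so macrophage RNA lies in both groups compared below. The named CD4 group therefore holds cells with CD8 and gamma-delta markers, and its values are not those of CD4 T cells alone. At a minimum of 10 cells, chosen after the data were seen, GA-aFuc against N297A gave 17 genes up and 5 down, and 7 and 2 without the top cell of each gene. For N297A against Untreated, 6 up and 7 down became 0 by edgeR without the top cell (94 at an unadjusted p under 0.05; no other tool was run).

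Tregs were compared with CD4 T cells in the 4 Untreated and N297A mice with at least 10 cells of each type, a minimum chosen after the data were seen, with mouse as a block. Of 2004 genes tested, 75 were higher and 80 lower in Tregs by at least 1 on the log2 scale. Higher genes included the integrin Itgb8, which activates TGF-beta (5.48 ± 0.69, log2 difference ± SE, adjusted p = 7.8e-05), the repair factor Areg (4.39 ± 0.44), and Izumo1r, the folate receptor 4 of regulatory cells (3.94 ± 0.43). Also higher were the cytokine gene Il10 (3.37 ± 0.48), the tissue homing receptors Ccr2 (3.34 ± 0.48) and Itgae (3.20 ± 0.52), and Klrg1 (3.01 ± 0.53). The myeloid genes Lyz2 (1.70 ± 0.40) and Cxcl10 (1.81 ± 0.33), chosen after their values were seen, were higher as well, so RNA of myeloid cells may add to the Treg values of Ccr2 and other genes that such cells express. Ccr2 was at 489 CPM in Tregs, 117 in CD4 T cells, 440.3 in monocytes and 65.5 in macrophages, and its source was not tested. Classical Treg genes were higher too: Ikzf2 (2.23 ± 0.38), the interleukin 2 receptor Il2ra (2.22 ± 0.31), Ctla4 (1.58 ± 0.32) and Icos (1.17 ± 0.26). Foxp3 itself did not pass (3.59 ± 1.07, adjusted p = 0.118), and neither did Gzmb (3.43 ± 0.81, adjusted p = 0.0924), Tnfrsf1b (0.44 ± 0.37, adjusted p = 0.494) or Tgfb1 (-0.41 ± 0.33, adjusted p = 0.476). Lower genes included the CD30 ligand Tnfsf8 (-5.19 ± 0.56, adjusted p = 2.99e-05), Aff3 (-5.09 ± 0.64), the RANK ligand Tnfsf11 (-4.37 ± 0.67), Bach2 (-4.24 ± 0.48) and the checkpoint receptor Pdcd1 (-2.40 ± 0.43). Genes that define the deposited clusters are among these, so the comparison describes the named groups, of which the CD4 T cells include cells with Trdc or Cd8a. Without N297A replicate 2, 83 genes passed in place of 155.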

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

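Of the tests below, the fold of NK markers, the NK cluster mix and the fold of neutrophil markers were set before their result was seen, and the others only after it; no group held the 4 mice that a test for an outlying mouse needs.

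Human genes beside the Fc gamma receptors gave counts in the annotated cells although no comparison uses them: ATF6 had 22709 UMIs, DUSP12 20222 and FCRLB 13433. Of the barcodes outside the annotation that had at least 1000 UMIs and 1 dominant hashtag, 72 of 469 in the GITR/Syn GA-aFuc mouse (15.4%, 95% Clopper-Pearson interval 12.2 to 18.9%) were named neutrophils by the fixed markers, against 3.46 to 5.30% in the other 5 mice.

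Tregs were a smaller share of cells in both mice given an Fc-enhanced antibody. Loss of barcodes with at least 1000 UMIs and 1 dominant hashtag through the authors' cell filtering is argued against. Among such barcodes outside the annotation, those with Cd3 and Foxp3 UMIs were 0.1% (1 of 1000, interval 0.00253 to 0.556%) in these mice and 1.76% (33 of 1876, interval 1.21 to 2.46%) in the others. With the annotated cells included they were 0.210% (8 of 3812, interval 0.0906 to 0.413%) in these mice and 1.23% (96 of 7794, interval 0.999 to 1.5%) in the others. Dilution by cells other than T cells is argued against, though weakly, by the share of Tregs among T cells. It was 1.86% (3 of 161, interval 0.386 to 5.35%) and 1.69% (3 of 177, interval 0.351 to 4.87%) in these mice. The lowest of the others had 4.87% (11 of 226, interval 2.45 to 8.54%), so the intervals overlap. Dilution by more CD8 or CD4 T cells is not covered by this share. An effect of the antibodies, the difference the design names, is consistent with the cells of the deposited table outside this library, where Tregs were 0.0725% (5 of 6894, interval 0.0236 to 0.169%) with the Fc-enhanced antibodies and 0.535% (19 of 3549, interval 0.323 to 0.835%) otherwise. These cells carry no map to mice. The labels give 3 mice per treatment in the design, of which 1 or 2 are in this library, so few mice would stand behind the pooled cells. Loss of Tregs through Fc-enhanced antibodies stays a hypothesis.

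Ccl5 and 4 other genes were lower in NK cells of both mice given an Fc-enhanced antibody (median log2 change -1.20). Dilution of NK RNA by other RNA is argued against by the 6 NK markers, whose median change was -0.11 (range -0.48 to -0.05). A shift among the 5 deposited NK clusters stays open: with equal cluster mixes the Ccl5 difference was -0.89, against -1.53 with each mouse's own mix. In clusters 19 and 26, where Ccl5 was highest, both mice lay below all others. In clusters 48 and 58, at low levels, both lay above all others. There they held 242 and 159 CPM against at most 136, and 83.6 and 42.4 CPM against at most 34.9. An effect of the antibodies cannot be told apart from differences between single mice, since each Fc-enhanced antibody had 1 mouse.

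Slpi, Cxcl1, Nos2 and other genes were higher in monocytes of the same mice (18 genes, median log2 change 0.94). Slpi was mainly high in the GITR/Syn GA-aFuc mouse: with that mouse left out its log2 change was 0.62. Neutrophils among the monocytes, which a CD45 sort keeps, stay undecided by marker folds. The median log2 change of 5 markers was 2.05, but Cxcr2, S100a8, S100a9 and G0s2 reached at most 9.56 CPM, too near 0 to weigh, and Csf3r, at 49.7 to 62.7 CPM in all mice, had a change of 0.050. They are argued against as the whole source by removal of the 73 of 2486 monocytes with a UMI of S100a8, S100a9, Cxcr2 or Retnlg, which left a median of 0.95 and Slpi at 585 CPM in the GITR/Syn GA-aFuc mouse. That 1 cell per gene and mouse carries the UMIs is argued against for the 18 genes as a set. Removing the top cell of each gene left a median of 0.96 and 14 of the 18 genes past the threshold. Whether several cells per gene carry them was not tested. An effect of the antibodies again rests on 1 mouse per antibody and remains open.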

How the results depend on the processing

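The comparison of Fc-enhanced with other mice, the removal of the top cell of each gene and the Treg and CD4 T cell minimum of 10 cells were chosen only after the results were seen. Comparisons are numbered as 1 (N297A against Untreated), 2 (GA-aFuc against Untreated), 3 (GITR/Syn GA-aFuc against Untreated), 4 (GA-aFuc against N297A), 5 (GITR/Syn GA-aFuc against GA-aFuc) and 6 (Fc-enhanced against other mice), and the cause of each change was not tested unless named. The 28, 43, 45, 19, 19 and 35 genes past the threshold over 5 cell types became 7, 20, 22, 6 and 6 with DESeq2 in comparisons 1 to 5. With limma-voom they were 21, 12, 7 and 22 in 2, 3, 5 and 6. An adjusted p under 0.1, a looser threshold by construction, gave 47, 65 and 65 in 1, 2 and 6. A mean count of 10, which tests fewer genes, gave 9, 10 and 23 in 1, 5 and 6. No filter gave 156, 305, 189 up with 108 down (3.0e+02 in sum), 142, 121 and 295. Only the 2 treatments gave 8, 203, 231 and 30 in 1 to 4. Without the top 5% of cells by UMIs comparisons 1, 4, 5 and 6 had 61, 29, 29 and 55. Removing the top cell of each gene gave 28, 22 and 8 in 2, 3 and 5. Upper-quartile normalization gave 26 in 3, and thinned totals gave 6 in 5. Leaving out each mouse in turn gave 3 to 198, 42 to 180, 34 to 205, 24 to 132, 8 to 79 and 42 to 278. The extremes of 1 came without Untreated replicate 2 (3) and N297A replicate 2 (198); without N297A replicate 1 the counts were 148, 180, 205, 132, 79 and 278, and without N297A replicate 2 comparisons 2, 3, 5 and 6 had 144, 205, 64 and 93. Without Untreated replicate 1 comparisons 5 and 6 had 8 and 66, and without Untreated replicate 2 comparison 5 had 10. With 1 mouse of a pair left out, 1 residual degree of freedom stays and the lone mouse is assumed to vary like the other groups. The 16, 14, 28, 11, 16 and 21 list calls became 0 with an estimated correlation and 0 with fry in all 6; with mice left out they ranged over 12 to 20, 12 to 19, 26 to 31, 11 to 17 (17 without N297A replicate 1), 14 to 19 and 10 to 30 (10 without the GITR/Syn GA-aFuc mouse). The Treg share difference of N297A from Untreated turned from 0.720 to -0.45 percentage points with marker naming, and that of cDC2 to -1.18. The cells named Tregs by markers held 100 deposited CD8 T cells beside 60 deposited Tregs. With mice left out the Treg difference was 0.548 to 0.892, and -1.08 to -0.768 for Fc-enhanced against other mice. Subtracting the level in CD8 T cells, as an estimate of free RNA in cells, took FCGR3A to 154 CPM in macrophages and 11.6 CPM in NK cells. With mice left out Tnfrsf18 stayed at 801 to 937 CPM in Tregs, 323 to 375 in CD4 T cells, 239 to 262 in CD8 T cells and 134 to 149.9 in NK cells. FCGR3B in macrophages stayed at 3541 to 3691, FCGR2A at 1018 to 1098, FCGR1A at 209.6 to 234, FCGR3A at 233 to 242 and in NK cells at 78.8 to 107, and FCGR2B at 1066 to 1099.6 in monocytes and 1301 to 1429 in cDC2. The 155 genes of Tregs against CD4 T cells became 91 with DESeq2, 304 without a filter and 83 to 174 with mice left out (83 without N297A replicate 2). Log2 changes that turned with the top cell removed were Gzmg in CD8 T cells (GA-aFuc against Untreated, -0.013), Hspa1a and Hspa1b in NK cells (GITR/Syn GA-aFuc against Untreated, -0.27 and -0.076), Ccl2 in NK cells (GA-aFuc against N297A, -0.14), and Cxcl2 and Ccl2 in NK cells (GITR/Syn GA-aFuc against GA-aFuc, 0.13 and 0.15). Those that turned without the top 5% of cells were Satb1 in monocytes (GITR/Syn GA-aFuc against Untreated, -0.32), Ccl12 in CD8 T cells (GA-aFuc against N297A, -0.78), and, for GITR/Syn GA-aFuc against GA-aFuc, C1qa in NK cells (0.023) and Top2a, H1f5 and Pclaf in cDC2 (0.43, 0.43 and 4.63). For Fc-enhanced against other mice, Fabp5 in monocytes ranged from -0.080 to 1.19, Tnfsf8 in CD8 T cells from -6.81 to 0.56 and Stmn1 in cDC2 from -3.16 to 0.074, each turned without the GITR/Syn GA-aFuc mouse, and Ccl7 in NK cells from -0.23 to 2.33, turned without the GA-aFuc mouse. Of values of genes named by the rule and past the threshold, 849 of 2493 lost it over all settings: 114 of 164 with DESeq2, 113 of 170 with limma-voom, 88 of 162 without the top cell, and 115 and 114 of 170 without Untreated replicates 1 and 2. Counts per cell type moved by over 1.5 times or to or from 0 in 304 cases and not in 272. Over all named values, most of which did not pass to begin with, 5500 stayed on their side, 366 gained and 889 lost the threshold; 187 receptor tests kept theirs and 11 ranks did not move. For the other shares, which cannot reach the threshold, only the direction was followed: 39 differences kept it and that of cDC2 turned. With 1 mouse left out 4 receptor tests gained the threshold: FCGR3A in CD8 T cells against NK cells (-0.43, adjusted p = 0.0154, without the GA-aFuc mouse), FCGR3B (-0.42, adjusted p = 0.00139, without the GITR/Syn GA-aFuc mouse) and FCGR2B (0.47, adjusted p = 0.00694, without N297A replicate 1) in the same pair, and FCGR3B in Tregs against CD8 T cells (2.44, adjusted p = 8.42e-09, without Untreated replicate 1). FCGR2B in Tregs against CD8 T cells lost it without Untreated replicate 2 (1.95, adjusted p = 0.0506), and FCGR3A there, which did not pass, turned to 0.17 and 0.66 without Untreated replicate 1 and N297A replicate 1 and lay at -0.75 without N297A replicate 2. The filter at 500 genes and 10% mitochondrial UMIs removed 0 cells and so tests nothing. The alternatives without a map of mice and with other cluster resolutions were not run, since both the map and the names were there. No paired analysis was possible because mice of different treatments have no pairing (the replicate number that the 2 GEO samples share marks 1 library). In simulated data for GA-aFuc against Untreated, dendritic cells gave 17% and CD8 T cells 33.3% of 2-fold changes. NK cells gave 44.9%, macrophages 45.5% and monocytes 49%, and whether depth sets these rates was not tested. Tregs and CD4 T cells fall under 20 cells in most mice.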

Other observations

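The genes and values in this part were chosen only after the results were seen. Of 9 redox and iron-handling genes looked at in monocytes of the GITR/Syn GA-aFuc mouse, 4 passed the threshold against the Untreated mice. Gclm rose (1.84 ± 0.20, log2 change ± SE, adjusted p = 0.00940), as did the peroxiredoxin Prdx1 (0.93 ± 0.13, adjusted p = 0.0355) and the ferritin chains Ftl1 (0.67 ± 0.09, adjusted p = 0.0355) and Fth1 (0.55 ± 0.09, adjusted p = 0.0382). Hmox1, the heme oxygenase, was at 589 CPM in this mouse, with 2034 UMIs in 158 cells, and at 40.9 and 59.9 CPM in the Untreated, 88.5 and 51.3 in the N297A and 68.0 in the GA-aFuc mice, yet its test did not pass (3.53 ± 0.38, adjusted p = 0.161). With the top cell of each gene removed, the 1 other setting read for Hmox1, it passed (log2 change 3.79, adjusted p = 2.17e-06), so its call depends on that setting. Gclc (1.11, adjusted p = 0.179), Srxn1 (1.23, adjusted p = 0.251), Txnrd1 (0.59, adjusted p = 0.595) and Slc7a11 (1.58, adjusted p = 0.764) did not pass. Arg1, an arginase of suppressive myeloid cells, was at 879.6 CPM in the GA-aFuc and 556 CPM in the GITR/Syn GA-aFuc mouse and at 125, 238, 361 and 202 CPM in the Untreated and N297A mice, which did not pass either (GA-aFuc against Untreated 2.27, adjusted p = 0.705).

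Gm42031 was higher in every larger cell type of the GA-aFuc mouse. Its macrophages held 108 CPM with a UMI in 59.5% of cells, against 11.7 to 14.7 CPM in the other 5 mice. In the same mouse monocytes held 108, CD8 T cells 57.3, NK cells 47.4 and cDC2 53.1 CPM.

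The cells of the deposited table outside this library, given by treatment without mice, had Tregs at 0.624% in Untreated, 0.448% in N297A, 0.0922% in GA-aFuc and 0.0549% in GITR/Syn GA-aFuc. Macrophages were 53.3%, 47.5%, 56.1% and 57.5% of them, monocytes 27.3%, 36.2%, 28.0% and 29.5%, and NK cells 7.20%, 7.51%, 5.26% and 4.59%, in the same order. In this library NK cells were 9.17% of the GA-aFuc and 5.37% of the GITR/Syn GA-aFuc mouse, against 7.11 to 11.2% in the Untreated and N297A mice, so only the GITR/Syn GA-aFuc mouse lay below them.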
